A study of Mus musculus with 12 samples.

How the data were processed

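Haemogenic endothelium was grown from mouse embryonic stem cells of strain 129. Per the labels' protocols, FLK1+ cells were taken from embryoid bodies at day 3.25 and kept for 2 days in liquid blast culture, then isolated again either by flow cytometry (cKIT+ TIE2+ CD41-) or by FLK1. Genomic DNA was extracted, prepared by a DamID protocol and made into barcoded SOLiD libraries, per the labels' protocols. The genome build was mm9, per the submitters' processing notes. The aligner, the rule by which regions were called, the comparison of Runx1b::Dam with Dam, the gene annotation and the rule that assigns a region to a gene are not given in the sources used here.

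Samples were grouped by the titles in the labels into 2 lines of 6 libraries, each with 3 biological replicates and 3 libraries called technical replicates. The labels give every library called a technical replicate another way of sorting (FLK1) than the library it repeats (flow cytometry). Each line has 2 libraries sorted by flow cytometry and 4 selected for FLK1, so the sort does not separate the lines.

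The authors deposited 1 table, with a read count for each gene, per the file headers, which is a whole number summed over all regions assigned to that gene. The table's second value is a signal, the read count per kilobase, per the file headers, and in all 5867 genes it equalled the read count divided by the summed length of the gene's regions within 0.006. It is not scaled to library size. There are 0 other columns of values per sample. Region boundaries lie on a 50 bp grid, and coordinates are printed as deposited. Printed widths are end minus start, whereas the summed length behind the reads per kilobase counts both end positions of each region.

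The planned test between the lines needs values per library and was not made, since the table has 1 value per gene. The comparisons therefore describe the set of regions. Gene symbols were matched to a RefSeq table of assembly GRCm38.p6 by symbol, and by synonym for protein-coding genes, on the same chromosome. Of the 4771 protein-coding genes deposited by the authors, 4678 (98.1%) matched. That table is of another build than the regions, so it gave only names, chromosomes and gene lengths, and none of its coordinates are printed. All 21887 protein-coding genes in it formed the background, of which 4581 had a region.

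The 17 gene lists, the tests and the rule for named genes were fixed before the data were examined. The lists cover matrix, guidance, focal adhesion and migration, integrin and other adhesion genes, endothelial genes, transcription factors of blood development, blood cell genes, TGF-beta and BMP, Notch and Wnt genes, and genes of heart muscle, smooth muscle, stem cells, neurons, hepatocytes and ribosomal proteins. Each was tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 17 lists and a threshold of 0.05. Each was also set against 10000 random lists matched on gene length in 10 strata, with a Mantel-Haenszel odds ratio and a permutation p whose smallest value is 0.0001. Reads per kb of list genes were compared with those of other genes with a region by a permutation test of the medians with 100000 resamples, two-sided. This test was planned on regions, and was run on genes because the table gives reads per gene. Only 3952 of the 8133 regions (48.6%) have a read count of their own. It came from a gene with a single region, or by subtraction where the counts of a gene's other regions were known. These were used for chromosomes, with 20000 permutations and 2000 bootstrap draws. Regions per chromosome were to be set against chromosome length, and the share of genes with a region was used in its place. Shares have exact Clopper-Pearson intervals and read counts exact Poisson intervals at 95%, which cover counting error only. At the median of 1883 reads the interval is 4.54% to each side.

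Genes were named by a fixed rule. It takes up to 4 members of each list with the most reads per kb, the 10 genes with the most regions, and Runx1, Gfi1, Gfi1b and Spi1. It also takes the 10 regions with the most reads per kb, here among regions with a read count of their own. Pou5f1, Nanog and Sox2 and all gene families were named after their values were seen, and 2 of these families are not reported here.

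The list tests were tested on simulated data over 21887 genes in 40 simulations. A list was called when its p, adjusted over the lists, was under 0.05. With regions placed by gene length alone, Fisher's exact test called 1.76% of list tests and 4.50% in the 5 adhesion and migration lists. The length-matched test called 0.294% of list tests. Gene length alone thus led Fisher's exact test to more calls than the length-matched test, and its share was higher in those 5 lists. With the odds raised by a factor of 4 in those 5 lists, Fisher's exact test called 99.0% and the length-matched test 83.5%. The median matched odds ratio was 4.04. The test of the medians was simulated on all 5867 genes of the table, not on the 4581 protein-coding genes it was applied to. In 40 simulations it called 2.50% of lists of 22 genes at no difference and 100% at a 1.5-fold difference, at an unadjusted p under 0.05.

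Alternatives covered the background, length matching, the stronger part of the regions, genes with 2 or more regions, autosomes alone, regions assigned to a single gene, and read counts in place of reads per kb. Motif content and distance to transcription starts were not analysed here, since no mm9 genome or annotation was used. All computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.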

Results

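Binding of Runx1b, an isoform of the blood transcription factor Runx1, was profiled by DamID-seq in haemogenic endothelium, the endothelial population from which blood cells emerge. In DamID the protein is fused to the bacterial Dam methylase, which methylates adenines in GATC sequences near the places where the fusion protein sits, and the methylated fragments are sequenced. The labels describe 12 libraries from cells of 2 mouse embryonic stem cell lines without functional Runx1, 6 from a line with the Runx1b::Dam fusion and 6 from a line with Dam alone. Each line had 3 biological replicates and 3 further libraries called technical replicates. In each line 2 libraries came from cells sorted by flow cytometry as cKIT+ TIE2+ CD41-, and 4 from cells selected magnetically for FLK1, a receptor of blood and vessel progenitors. The deposited table gives 1 read count per gene and none per library, so the depth of each library is unknown, no value has a replicate error, and the Dam background cannot be set beside a gene's reads. Which libraries the reads came from is not given in the sources used here, so the reads per kilobase printed here describe signal within regions and are not an enrichment over Dam.

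The table listed 5867 genes with 8133 distinct regions of the mm9 build. Of these genes, 4771 were protein coding, 326 were processed transcripts, 288 were long intergenic RNAs and 196 were pseudogenes. The regions had a median width of 2100.0 bp (quartiles 1650.0 and 2850.0 bp) and covered 20.3 Mb, with a median gap of 67.7 kb between neighbours. A gene had a median of 1883 reads, for which counting error alone gives a 95% Poisson interval of 1799 to 1970.0, and a median of 683 reads per kb of its regions (quartiles 515 and 918). Reads amplified by PCR are not independent molecules, so all counting intervals given here are lower limits of the error. A single region was assigned to 4239 genes (72.3%), and 648 genes had 3 or more.

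The series title concerns a cell adhesion and migration programme, and genes of 5 fixed lists address it. Genes of the extracellular matrix, of axon and vessel guidance, of focal adhesion and cell migration, of the integrins and of other adhesion molecules all had a region more often than protein-coding genes at large, of which 4581 of 21887 (20.9%) had one. Among matrix genes 19 of 25 (76.0%) had a region. They included Col4a1 and Col4a2, the neighbouring genes of the main basement membrane collagen, Mmp14, a membrane-anchored collagenase, and Sparc, a collagen-binding secreted protein. Among guidance genes it was 22 of 30 (73.3%), with Ephb4, a venous ephrin receptor, Nrp1, a co-receptor for semaphorins and VEGF, the ephrin receptor Epha2 and the semaphorin receptor Plxna1.

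Col4a1 had 7 regions with 38222 reads on chromosome 8 between 11233548 and 11310898, at 1379 reads per kb (95% Poisson interval 1366 to 1393), and Col4a2 had 3 regions between 11313848 and 11383898 at 1570 (1548 to 1592). Mmp14 had 1234 reads per kb, with 1 of its 2 regions shared with Mrpl52, and Sparc had 1140.1 over 4 regions. Ephb4 reached 1988 reads per kb, Nrp1 1334, Epha2 766 and Plxna1 734.

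Focal adhesion and migration genes had a region in 23 of 38 cases (60.5%). The highest reads per kb in this list were 2273 at Ilk, the integrin-linked kinase, whose region was also assigned to Taf10, 1482 at Ptk2, the focal adhesion kinase, 1289 at Tln1, which couples integrins to actin, and 1249 at the kinase Src. Of the integrin subunits 15 of 26 (57.7%) had a region, led by Itgb1, the beta chain shared by most matrix-binding integrins, at 1452 reads per kb, followed by Itga5, the alpha chain of the fibronectin receptor, at 1212, Itgb4 at 1065 and Itga3 at 974. Of the other adhesion molecules 15 of 32 (46.9%) had one. Their highest values were 1601 reads per kb (1573 to 1629) at Cdh5, the endothelial cadherin, with 2 regions on chromosome 8 between 106618398 and 106627398, 1506 at the junctional protein F11r, 1489.8 at Icam2 and 1146 at the nectin Pvrl2. For F11r, 1 of 2 regions was shared with Gm17520.

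By Fisher's exact test, two-sided and adjusted by Benjamini-Hochberg over 17 lists, the odds ratio of having a region was 12.01 for matrix genes (95% interval 4.61 to 36.8, adjusted p = 3.23e-08) and 10.4 for guidance genes (4.47 to 27.1, adjusted p = 9.23e-09). By the same exact test it was 5.82 for focal adhesion and migration genes (2.90 to 11.997, adjusted p = 5.30e-07), 5.16 for integrins (2.21 to 12.4, adjusted p = 0.00011) and 3.34 for other adhesion molecules (1.55 to 7.12, adjusted p = 0.00248). Genes are not independent replicates, so these values describe this set of regions and not a repeat of the experiment. When protein-coding genes were cut into 10 classes by length, the share with a region rose from 3.24% in the shortest class to 45.3% in the longest. Against random lists matched on length the odds ratio was 11.8 for matrix genes, 4.61 for guidance genes, 3.66 for focal adhesion and migration genes, 3.48 for integrins and 2.09 for other adhesion molecules. The adjusted permutation p was 0.0414 for the other adhesion molecules, 0.0034 for integrins and 0.00034 for the remaining lists. Among genes above the median reads per kb the odds ratio of matrix genes was 5.66 (10 of 25) and guidance genes no longer passed (2.12, 6 of 30), and other adhesion molecules no longer passed with 2 or more regions required (2.70) or with predicted and receptor genes left out of the matched background (1.99). With all genes as background, non-coding ones included, the odds ratios of these 5 lists were higher, from 7.73 for other adhesion molecules to 27.8 for matrix genes. The lists hold protein-coding genes, and only 5126 of 49943 genes of any type had a region. That background therefore raised the odds ratio of every list, ribosomal proteins included (from 0.515 to 1.19), and the rise is not particular to these 5.

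**Figure D1:**
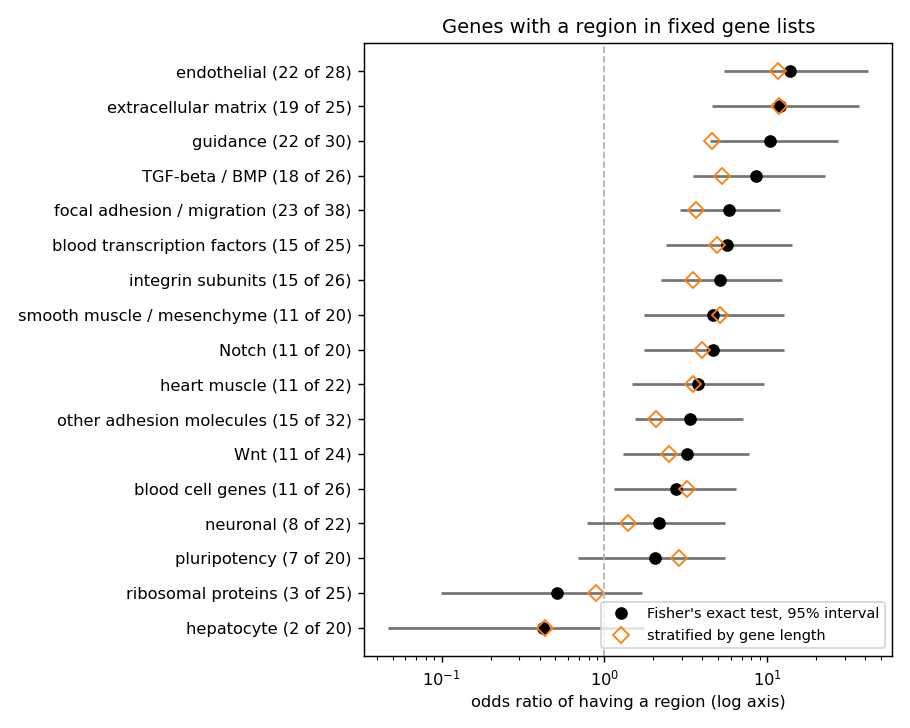
Odds ratio of having a region (log axis) for each of the 17 fixed gene lists, with the number of members that had a region. Filled circles and bars are Fisher's exact test with its 95% interval and open diamonds are odds ratios stratified by gene length. Endothelial genes have the highest Fisher odds ratio (13.9) and hepatocyte genes the lowest (0.420).

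Of the 17 fixed lists, endothelial genes had the highest share with a region, 22 of 28 (78.6%). Besides Cdh5, the highest values were at Eng, a TGF-beta co-receptor of vessels, with 1612 reads per kb, at Sox7, a transcription factor of early endothelium, with 1526, and at Tal1, a transcription factor required for blood formation, with 1513 (1491 to 1534) over 2 regions on chromosome 4 between 114730709 and 114748959. For Eng, 1 of 2 regions was shared with AL772271.5. The odds ratio was 13.9 (5.47 to 42.0, adjusted p = 1.85e-09 by Fisher's exact test, two-sided), and 11.6 against length-matched lists. Of the 28 endothelial genes 9 also stood in another list, so the lists are not independent of each other.

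Transcription factors of blood development had a region in 15 of 25 cases (60.0%), and surface receptors and effectors of blood cells in 11 of 26 (42.3%). After Tal1, the highest reads per kb among the transcription factors were 1341 at Zfpm1, a GATA cofactor, 1317 at the corepressor Cbfa2t3 and 1268 at Lyl1, a relative of Tal1. Zfpm1, Cbfa2t3 and Lyl1 lie on chromosome 8, whose regions had 1.36 times the median reads per kb of other autosomes. The 3 regions of Zfpm1 and the 3 of Cbfa2t3 were also assigned to the gene model AC114005.5, and the single region of Lyl1 was also assigned to Nfix and Trmt1. Among blood cell genes, Gp1ba, a platelet adhesion receptor, had 2088 reads per kb, the lysosomal protein Laptm5 1531, the actin regulator Was, on chromosome X, 803 and Cd34, a progenitor surface protein, 801. Fisher's exact test, two-sided, gave an odds ratio of 5.68 for the transcription factors (2.39 to 14.2, adjusted p = 6.75e-05) and 2.77 for the blood cell genes (1.15 to 6.47, adjusted p = 0.0175), and the length-matched odds ratios were 4.93 and 3.22 (adjusted permutation p = 0.0017 and 0.00912). With regions assigned to a single gene only, 11 of the 25 transcription factors had one (odds ratio 3.59), and with 2 or more regions required their odds ratio was 9.77. The blood cell result did not pass among genes above the median reads per kb (odds ratio 2.02), with 2 or more regions required (1.90) or with autosomal genes alone (2.25), the last chosen after the data were seen.

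Runx1 itself, gene ENSMUSG00000022952, had 7 regions spread over 203 kb of chromosome 16 between 92627364 and 92829914, with 11076 reads and 696 reads per kb, close to the median of all genes. Both lines lack functional Runx1 and the fusion line carries Runx1b sequence of its own, and reads from that sequence cannot be separated from reads of the locus. Gfi1 and Gfi1b, repressors that silence endothelial genes as blood forms, each had 1 region, for Gfi1 on chromosome 5 between 108152879 and 108155279 with 1145 reads (477 reads per kb, shared with A430072P03Rik) and for Gfi1b on chromosome 2 between 28473624 and 28475674 with 1128 reads (549.98 reads per kb). The gene of the myeloid factor PU.1, named Sfpi1 in the table, had 1 region on chromosome 2 between 90936274 and 90937824 with 524 reads. Its 338 reads per kb (309.5 to 368) were higher than in only 9.44% of the listed genes. Whether these regions lie in exons, introns or promoters was not analysed here, as no mm9 annotation was used.

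**Figure D2:**
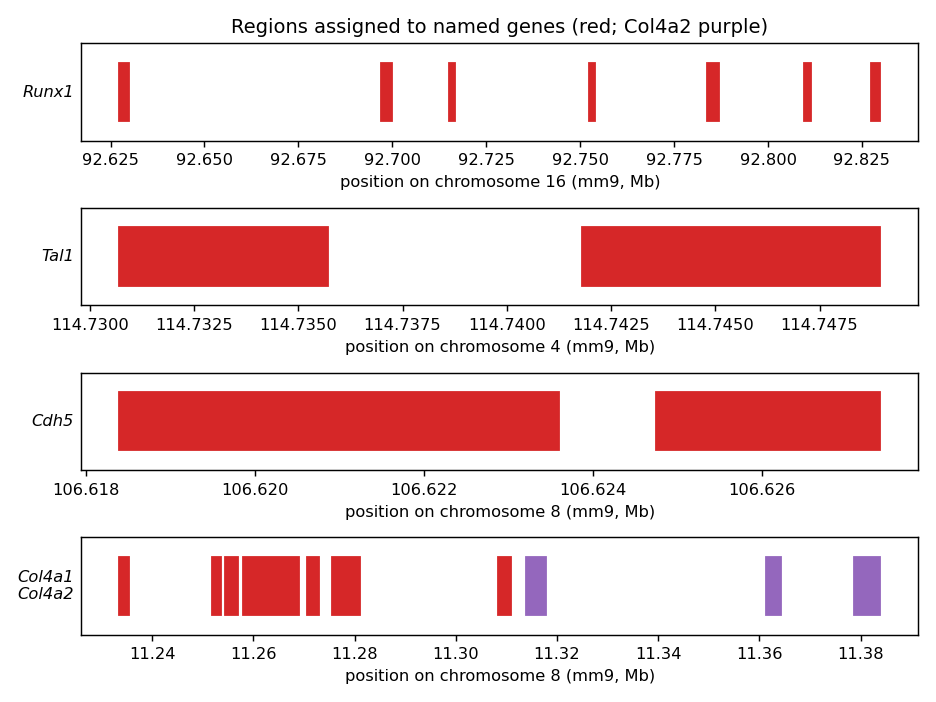
Positions in mm9 (Mb) of the regions assigned to Runx1 on chromosome 16, Tal1 on chromosome 4, Cdh5 on chromosome 8 and the neighbouring Col4a1 (red) and Col4a2 (purple) on chromosome 8, each box drawn to scale from the start to the end of a region. The 7 Runx1 regions span 203 kb, and the 7 Col4a1 regions lie beside the 3 of Col4a2.

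Signalling genes also had a region more often than protein-coding genes at large. In the TGF-beta and BMP list 18 of 26 genes (69.2%) had one, with Id2 at 1778 reads per kb and Id3 at 1439, both BMP-responsive inhibitors of basic helix-loop-helix factors, the ligand Bmp2 at 1403 and the inhibitory Smad7 at 1306. In the Notch list it was 11 of 20 (55.0%), with the Notch target Hes1 at 1259 reads per kb, the receptor Notch2 at 1113, Numb, an inhibitor of Notch, at 992 and the co-activator Maml1 at 952. In the Wnt list it was 11 of 24 (45.8%), with the ligand Wnt11 at 1264, the receptor Fzd2 at 1153, the co-receptor Lrp6 at 845 and the transcription factor Tcf7l1 at 794. Fisher's exact test, two-sided, gave odds ratios of 8.53 (3.53 to 22.7, adjusted p = 5.30e-07), 4.63 (1.74 to 12.6, adjusted p = 0.00159) and 3.20 (1.30 to 7.75, adjusted p = 0.0128). Against length-matched lists they were 5.30, 3.98 and 2.52, and the Wnt list no longer passed (adjusted permutation p = 0.0644). With 2 or more regions required neither the Notch list (3.65) nor the Wnt list (1.32) passed, and among genes above the median reads per kb the TGF-beta and BMP odds ratio was 5.30.

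Genes of 2 other mesodermal lineages had a region more often than protein-coding genes at large as well. Heart muscle genes had one in 11 of 22 cases, with 2093 reads per kb at Nkx2-5 and 2028 at Gata4, transcription factors of the early heart, 1344 at the atrial myosin light chain Myl7 and 1160.2 at the transcription factor Hand2. Smooth muscle and mesenchymal genes had one in 11 of 20 cases, with the intermediate filament gene Vim at 1083 reads per kb, the myosin light chain kinase Mylk at 984 over 7 regions, the smooth muscle actin Acta2 at 970.3 and the receptor Pdgfra at 848. Fisher's exact test, two-sided, gave an odds ratio of 3.78 for heart muscle genes (1.49 to 9.63, adjusted p = 0.0036) and 4.63 for smooth muscle genes (1.74 to 12.6, adjusted p = 0.00159), with length-matched odds ratios of 3.50 and 5.16. Among genes above the median reads per kb the odds ratio of heart muscle genes was 5.87.

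In 4 lists the share of genes with a region did not pass the test. Stem cell genes had a region in 7 of 20 cases (odds ratio 2.04, 0.687 to 5.49, adjusted p = 0.185 by Fisher's exact test, two-sided), with values at Dppa4 (2167 reads per kb), Sall4 (1395), Tbx3 (1176) and Klf5 (708). The Tbx3 region was shared with Gm2301, and 1 of 2 Sall4 regions with Gm14261. Pou5f1, Nanog and Sox2 had none. Neuronal genes had one in 8 of 22 cases (2.16, 0.785 to 5.52, exact adjusted p = 0.133), among them Gria2 (1119.9), Camk2a (830.4), Gad2 (728) and Syt1 (667). Hepatocyte genes had one in 2 of 20 cases (0.420, 0.0472 to 1.75, exact adjusted p = 0.302), Trf (734) and Ahsg (134). Ribosomal protein genes had one in 3 of 25 cases (0.515, 0.0986 to 1.71, exact adjusted p = 0.335), Rpl11 (1577), Rps2 (1244) and Rpl3 (754). The Trf region was shared with Srprb and the Rps2 region with Ndufb10. Length matching did not bring any of these 4 lists past the test, with 0.0522 as the lowest adjusted permutation p, for the stem cell genes. With all genes as background, stem cell (4.71) and neuronal genes (5.00) did pass. That background raised the odds ratio of every list, hepatocyte genes (0.971) and ribosomal proteins (1.19) included, so these passes are not particular to the 2 lists.

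Among genes with a region, the difference in reads per kb between list genes and other genes passed the test for 0 of the 17 lists after adjustment. Heart muscle genes came closest, with a median of 1068 reads per kb over 11 genes against 686 over the other 4570 (permutation test of the medians, two-sided, p = 0.00377, adjusted p = 0.0641). Reads per kb were also divided by the median of each gene's chromosome, a scaling chosen after the data were seen. The excess was then 0.314 for heart muscle genes (permutation p = 0.0503, adjusted p = 0.214) and 0.324 for endothelial genes (permutation p = 0.00613, adjusted p = 0.104). Endothelial genes had a median of 883 over 22 genes against 686 (permutation test, two-sided, p = 0.0119, adjusted p = 0.101), focal adhesion and migration genes 819, matrix genes 742 and guidance genes 591. An alternative chosen after the data were seen used regions with a read count of their own, and no list passed in it. Matrix genes then differed by -122.8 reads per kb over 7 regions, in place of 55.5 (permutation test, p = 0.356). Guidance genes differed by 61.6 over 9 regions, in place of -95.8 (permutation p = 0.606). Focal adhesion and migration genes differed by 445 over 9 regions, in place of 133 (permutation p = 0.0061, adjusted p = 0.0831). Over genes, as in the main setting, the unadjusted p of the permutation test was under 0.05 for 3 lists. These were heart muscle, endothelial and ribosomal protein genes, the last with only 3 genes.

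Only the 3952 regions with a read count of their own could be ranked by reads per kb. Of these, the 10 with the most all lay at genes outside the fixed lists. Regions without such a count, among them those of Gata4, Tal1 and Cdh5, could not be placed in this ranking. The highest of the 10, with 8869 reads per kb (8757 to 8982), was assigned to Pfdn4, a subunit of the prefoldin chaperone. It lay on chromosome 2 between 170351074 and 170353774. Next, a region with 7221 reads per kb on chromosome 1 between 24618263 and 24623063 was assigned to the gene models Gm10222 and Gm10925, and the last of the 10, with 3020.0 on chromosome 2 between 22442824 and 22446074, to Myo3a and the pseudogenes Gm13339, Gm13340 and Gm13341. Both places are known for nuclear copies of mitochondrial DNA, so their reads are uncertain. Between them stood Bmp1, a procollagen proteinase (4763), Ifi30, a lysosomal thiol reductase (4460.3), 6430573F11Rik (3916), the kinesin gene Kifc3 (3493), AI467606 (3154), 1200009I06Rik (3083) and the long intergenic RNA Gm10809 (3056). The regions of Ifi30, 6430573F11Rik and Kifc3 lie on chromosome 8.

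More genes had several regions than a Poisson distribution gives. With 0.331 regions per protein-coding gene, a Poisson distribution within the 10 classes of gene length puts 283 genes at 3 or more regions, and 583 had that many. For 5 or more regions the numbers were 11.3 expected and 146 observed. No test was made, since neighbouring regions are not independent. Gene length also varies within a class, so the excess cannot be separated from length. Among the genes with the most regions were Tead1, a transcription factor of the Hippo pathway, with 14 regions over 189 kb, Msi2, an RNA-binding protein of blood stem cells, with 13, Sgms1, a sphingomyelin synthase, with 13, Frmd4a with 12, the tetraspanin Tspan9, Zmiz1 and the long RNA Pvt1 with 11 each, and Rere with 10. The gene model AC114005.5 had 59 regions spread over 4317 kb, 27 of them also assigned to 15 other genes, and the receptor gene Fgfr2 had 19 over 3032 kb, 12 of them also assigned to other genes.

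Regions on chromosome X had few reads, with a median of 129 reads per kb over 242 regions against 681 on the autosomes, a ratio of 0.189 (95% bootstrap interval 0.169 to 0.237). On chromosome Y the median was 23.6 over 6 regions. Chromosome 8 holds, among others, Cdh5, Col4a1, Col4a2, Itgb1, Nrp1, Hand2, Zfpm1, Cbfa2t3, Lyl1, Ifi30, 6430573F11Rik and Kifc3. It had the highest median, 912, which was 1.36 times that of the other autosomes (1.24 to 1.46). Chromosome 14 had 807 (1.20 times), chromosome 11 had 791 (1.18 times) and chromosome 16, with Runx1, had 580.1 (0.846 times). These 4 autosomes passed a two-sided permutation test over 21 chromosomes, with adjusted p = 0.00035, 0.000787, 0.00035 and 0.00507, and the values for chromosomes 8, 11 and X are the smallest that 20000 permutations can give. The share of protein-coding genes with a region differed among the autosomes (chi-square 106 on 18 degrees of freedom, p = 1.95e-14), from 15.8% on chromosome 7 to 27.1% on chromosome 12, and was 22.8% on chromosome X and 3.52% on chromosome Y. Neither genes nor neighbouring regions are independent, as 681 regions were assigned to 2 or more genes. The share was also not adjusted for gene length, so these tests describe differences among chromosomes and not their cause.

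**Figure D3:**
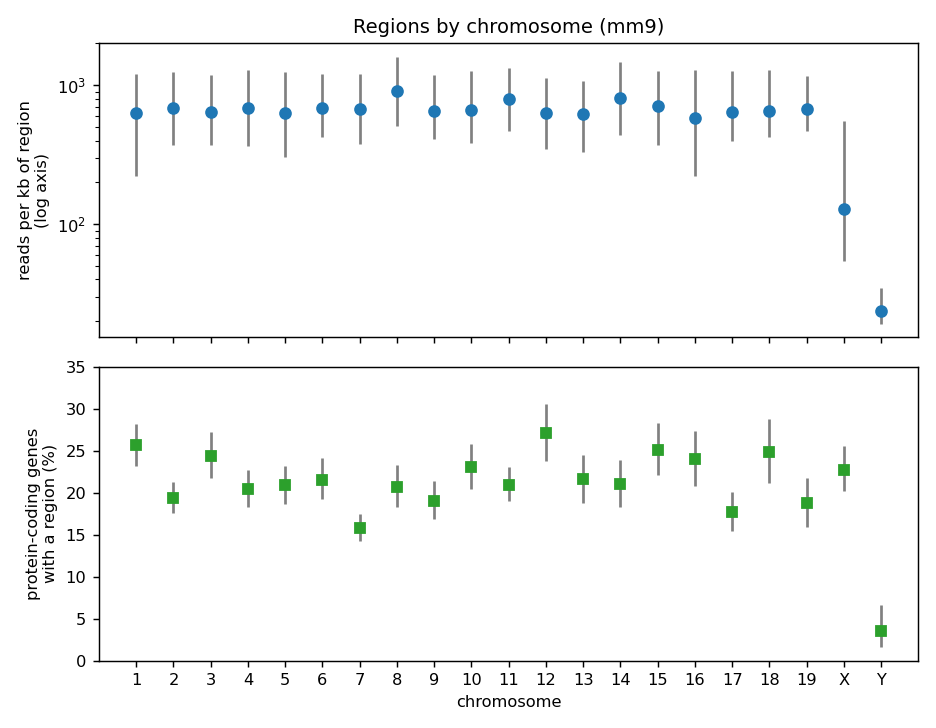
Upper panel, median reads per kb of the regions of each chromosome that have a read count of their own (log axis), with bars from the 10th to the 90th percentile. Lower panel, percent of protein-coding genes with a region and its 95% Clopper-Pearson interval. Chromosome X lies at 129 reads per kb and chromosome 8 at 912, while 22.8% of X genes and 20.7% of chromosome 8 genes have a region.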

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

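The tests with autosomes alone, with predicted and receptor genes left out, with 50 length strata, with regions of a single gene, with values scaled to the chromosome and with regions that have their own count were chosen after the data were seen. No paired analysis was possible because the table gives 1 value per gene and none per library, although the lines share replicate numbers. Of the odds ratios of the 17 lists, none past the threshold changed direction. All genes as background brought stem cell (4.71) and neuronal genes (5.00) past it, in a setting that raised the odds ratio of every list. Length matching lost the Wnt list (2.52), as did 50 strata (2.55), and leaving out predicted and receptor genes with matching lost it (2.34) and other adhesion molecules (1.99). Keeping only genes above the median of 683 reads per kb lost blood cell (2.02) and guidance genes (2.12). Counting only genes with 2 or more regions lost blood cell (1.90), other adhesion (2.70), Notch (3.65) and Wnt genes (1.32), and autosomes alone lost blood cell genes (2.25). The cause was not tested. Regions of a single gene changed no call, though the odds ratio of blood transcription factors fell to 3.59. From 9 to 15 lists passed over all settings, against 13. In strength, read counts in place of reads per kb brought 6 lists past the threshold, with median differences of 6817.5 reads for blood transcription factors, 4888 for focal adhesion, 4189.5 for endothelial, 3886 for heart muscle, 2169 for TGF-beta and BMP and 1558 for matrix genes, and a count grows with the number and width of regions. The other 2 strength settings changed no call, but the sign of differences that had not passed did change. With regions that have their own count it did for matrix (-122.8) and guidance genes (61.6), and stem cell genes moved from 21.7 to 477. With values scaled to the chromosome it did for stem cell genes (-0.161) and blood transcription factors (-0.0066), and with read counts for guidance (1008), Notch (-3.5), Wnt (-79) and neuronal genes (127). Regions numbered 8084 after merging within 1 kb, 7695 on autosomes and, by construction, 1976 in the stronger part of those with their own count. Motif, promoter distance, nearest start and 10 kb assignment settings were not run without an mm9 genome or annotation, nor were the settings for edgeR, DESeq2, filters, pseudocounts, technical replicates and left-out replicates, which need values per library. The unknown depth per library limits all values to a description of pooled regions.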

Other observations

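Protein-coding genes were also grouped into families by the start of their symbols, a grouping chosen after the data were seen, in which the integrin and semaphorin families share genes with the fixed lists. Of 258 families with 10 or more protein-coding genes, 8 had a region more often and 11 less often than expected by Fisher's exact test, two-sided, adjusted over the 258. Among the 8 were the numbered integrin alpha chains Itga (8 of 12, exact adjusted p = 0.021) and the tetraspanins Tspan (11 of 20, 0.021). Alpha chains with a letter after Itga, such as Itgav and Itgam, were not counted in that family. The transcription factors Klf (9 of 17), the phosphatases Ptpn (9 of 17), the semaphorins Sema (10 of 20) and genes named Cdc (14 of 32) each had an exact adjusted p of 0.0499. None of the 8 passed against length-matched lists, with an adjusted permutation p of 0.145 for Tspan and Klf.

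Chemosensory receptor families had almost no regions. Olfactory receptors (Olfr) had one in 6 of 1110 genes where length-matched lists gave 54.8, and vomeronasal receptors (Vmn) in 0 of 355 where they gave 36.2, each with a matched permutation p of 0.0001, the smallest possible, and an adjusted p of 0.0086. Predicted genes named LOC had 0 of 138 against 19.9. A gene that the authors' annotation lacks or names otherwise counts here as having no region, and reads shared among near-identical receptor copies are uncertain. Cytochrome P450 genes (Cyp) had 9 of 99 (Fisher adjusted p = 0.0461, matched adjusted p = 0.145).

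The tests of a single X copy, of a calling rule scaled to each chromosome, of an extra copy of chromosome 8 and of gene length over the 5 adhesion and migration lists together were chosen only after the results they bear on were seen, while length matching of each list was planned. Whether any of the following patterns differs between the 2 lines was not tested, because the table has no values per line.

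Regions on chromosome X carried a median of 129 reads per kb, 0.189 times that of autosomal regions (95% bootstrap interval 0.169 to 0.237). The interval argues against a single X copy in XY cells as the whole cause, since losing 1 of 2 copies would lower the reads less than this. Narrower regions on X, whose smallest width was 800.0 bp against 1200.0 bp or more on autosomes, are opposed as well, since among regions of at least 1550.0 bp the ratio was still 0.213 (0.157 to 0.403). A candidate explanation that stays open is a calling rule scaled to each chromosome, because the share of X genes with a region was 1.08 times the autosomal share (22.8% against 21.1%) in spite of the lower reads. If so, regions on X may have been admitted at a lower read density, and the reads per kb of X genes such as Was would not be comparable with those of autosomal genes.

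Regions on chromosome 8 carried 1.36 times the reads per kb of those on other autosomes. A wider minimum width on chromosome 8 is opposed by the ratio of 1.34 (1.23 to 1.45) among regions of at least 1550.0 bp, and a few very strong regions by the ratio of the 25th percentiles, 1.27 (1.12 to 1.40). An extra copy of chromosome 8, a gain seen in cultured mouse stem cells, cannot be told apart from other causes. Among these is a calling rule scaled to each chromosome, left open above for X, which was not tested for chromosome 8 by itself. Across the 19 autosomes, the smallest region width rose with the median reads per kb (Pearson 0.761, Spearman 0.751, permutation p = 0.0001 each). This comparison was not planned. Calling cutoffs that differ among chromosomes could give such a relation, but it does not exclude an extra copy. The smallest region width on chromosome 8, 1550.0 bp, was the largest of all chromosomes. With the regions cut along the chromosome into 6 parts of about equal number, the lowest ratio was 1.14 (1.03 to 1.33), in the first part, but the interval of the next part included 1 (1.22, 0.815 to 1.51), and the ratios of the last 2 parts were 1.66 and 1.57, the latter from only 9 regions. The values of Cdh5, Col4a1, Col4a2 and other chromosome 8 genes could thus be raised with their chromosome, whereas the share of genes with a region was 20.7% on chromosome 8 and 21.1% over all autosomes.

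The matrix, guidance, focal adhesion, integrin and other adhesion lists together had a region at 94 of 151 genes. Gene length is opposed as the whole cause, since length-matched lists gave 47.0 genes and the length-stratified odds ratio was 3.91 (permutation p = 0.0001, the smallest possible). Predicted and receptor genes in the background are opposed too, because without them 4 of the 5 lists passed against length-matched lists. Whether regions are more frequent at these genes than at signalling genes stays open, with 62.3% against 57.1% (40 of 70 Notch, TGF-beta, BMP and Wnt genes) and a length-stratified odds ratio of 1.11 (permutation p = 0.762, two-sided).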
